A study of Mus musculus with 15 samples.

How the data were processed

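RNA was sequenced from whole liver of wild-type mice in 15 libraries, 5 in each of 3 groups: control, methotrexate (MTX), and MTX with nitrate. The groups and replicate numbers were taken from the sample titles and treatment labels. The labels do not state that each library came from its own mouse, so the p-values measure the spread between these libraries. Per the labels' protocols, RNA was purified on silica columns and 1.3 µg of total RNA entered a SMARTer mRNA-seq library kit, whose strand setting the protocol does not give. Per the submitters' processing notes, the genome build was GRCm38 (mm10). The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here.

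The authors deposited 1 table of whole-number read counts per Ensembl gene, with 1 column per library and no normalisation. The table held 54532 genes with their symbols and GRCm38 coordinates, and 207 of them shared a symbol with another gene identifier. All 15 columns matched a library by label, and each row named a gene. Library totals ran from 16663967 to 19274497 counts. At the lowest total, a gene at a level of 2 CPM (counts scaled to library size) was counted 33.3 times, which carries a counting error of 17.3%, while the common biological coefficient of variation between libraries of a group was 0.223. The spread between libraries exceeded this counting error. The 30 pairs of libraries within groups were compared for duplicates, and their counts differed by 21.1 to 57.4 times the sampling variance.

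From the counts, genes were filtered with filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and 14219 genes were tested in edgeR 4.0.16 (R 4.3.3). A quasi-likelihood model over all 15 libraries gave the 3 groups a shared estimate of spread with 12 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Adjusted p-values of single genes come from this test throughout. Expression levels are TMM-scaled CPM, given as mean ± SD over 5 libraries, and log2 fold changes carry their standard errors.

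Before the data were examined, 40 gene lists were fixed from textbook knowledge of liver metabolism, stress, inflammation, Wnt signalling and cell types. The 36 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2). Camera used a preset inter-gene correlation of 0.01, and its p-values were adjusted over the 36 lists. Each list is given with its members called over all genes tested, the number called when adjusted over the list alone, and camera's adjusted p with a correlation estimated from the data.

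The genes named were also set by a rule fixed before the data were examined. It took up to 8 genes per direction and comparison with the largest fold changes among those called, at a mean of at least 2 CPM and with no overlap between the groups. It added up to 4 called members of each described list, or the 2 with the lowest p where none was called. It further added 14 fixed genes and 10 genes called in opposite directions by MTX and by nitrate. Some genes that the rule takes, or that belong to a described list, are not reported here by name. Genes named outside this rule are marked as chosen after their values were seen.

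Library measures and scores were compared with two-sided exact permutation tests over all 252 assignments of 5 against 5 libraries, whose smallest p is 0.0079. The MTX signature score was the mean log2 CPM of genes higher in the 10 MTX-treated libraries than in control, minus that of genes lower. Relations between comparisons that share libraries were set against 20 simulations without the effect and 20 splits of the shared libraries. The edgeR fit, the camera test and the signature score were tested on simulated counts first, and the other procedures were not. At a simulated 1.5-fold change, edgeR recovered 33 of 100 genes for MTX against control (14010 genes tested), 31 of 100 for MTX+nitrate against MTX (14026) and 48 of 100 for MTX+nitrate against control (14009). At 2-fold, it recovered 73, 76 and 74 of 100, with 1, 5 and 3 false calls in all.

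Alternatives fixed before the data were examined were median-of-ratios size factors, DESeq2 1.42.0, limma-voom, no expression filter, a stricter filter of at least 1 CPM in 5 libraries, a fit over 2 groups, a replicate block, stricter thresholds, other list tests and leaving out each library. A correction for transcript length and GC content was added after the data were seen. It fitted a smooth trend per library with mgcv 1.9.3 on the longest GENCODE M21 transcript of each gene and entered these trends as offsets. An exact permutation of list means was also added then. Reads of overlapping genes, near-identical paralogs and mitochondrial genes may be split differently by other counting settings, and this is stated where some such genes are named. Not marked there are Hspe1 (overlapped by Hspd1 at 4.35 times its level), Per3, Nav2, Prdx2, Nr1d1, Gpr182, Ccnd1 and Gm6136. Each overlaps another tested gene whose level is at least 0.2 times its own.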

Results

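The series measured how liver gene expression responded to methotrexate (MTX), a folate antagonist that can injure the liver, with and without dietary nitrate. RNA from whole livers of wild-type mice was sequenced in 15 libraries, 5 per group. The MTX mice received a single intraperitoneal dose of 20 mg/kg, and their livers were taken 24 h later. The MTX+nitrate mice received the same dose after 5 days on water with 2 mM nitrate, an anion that the body can reduce to nitrite and nitric oxide. No group received nitrate alone, so the effect of nitrate was measured only on top of MTX. Control libraries 1 to 5 held 17772735, 17551515, 18010810, 18626574 and 16663967 counts. MTX libraries 1 to 5 held 17373279, 17538721, 17933058, 17348176 and 17685964, and MTX+nitrate libraries 1 to 5 held 17789001, 19274497, 18889764, 17273003 and 17823477. Levels below are mean ± SD CPM over 5 libraries, and log2 fold changes are given ± SE.

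The groups separated on the first 2 principal components of the tested genes. The first (16% of the variance) placed control libraries between -34.69 and -13.57, MTX libraries between 8.09 and 38.06, and MTX+nitrate libraries between -12.56 and 20.43. On the second (12.4%), MTX+nitrate libraries lay between -37.65 and -20.21 and all others between -0.51 and 21.71. Total counts, genes detected, and the shares of the 10 most abundant genes, mitochondrial genes, haemoglobins and ribosomal proteins gave 18 exact permutation tests, with a lowest adjusted p of 0.143. That value belonged to ribosomal protein genes, at 1.13 ± 0.104% of counts in MTX and 0.912 ± 0.0655% in control (exact p = 0.00794). This exact p is the smallest possible, and over 18 tests a single measure at it cannot pass after adjustment. The adjusted p-values therefore do not show that the groups were alike in these measures. A trend on transcript length, looked for after the data were seen, marked the MTX libraries. Within a library, the correlation across genes of expression deviation with transcript length was -0.179 ± 0.1 in MTX, 0.081 ± 0.096 in control and 0.0688 ± 0.08 in MTX+nitrate (MTX against either, exact p = 0.0159, adjusted p = 0.0239). Genes are not independent replicates in such a correlation. It lay between -0.239 and -0.209 in MTX libraries 1 to 4 and at 0.005 in MTX library 5. A trend on GC content was not confined to comparisons with MTX alone. Across genes, fold change correlated with GC content at 0.349 for MTX+nitrate against control. The value was 0.161 for MTX against control and 0.153 for MTX+nitrate against MTX. Long non-coding RNAs held 0.392 ± 0.022% of counts in MTX, 0.523 ± 0.045% in control (exact p = 0.00794) and 0.493 ± 0.051% in MTX+nitrate (exact p = 0.0159, adjusted p = 0.0239 for both).

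The first comparison asked what MTX did to the liver. Acute phase genes, which encode plasma proteins that hepatocytes release during inflammation, showed the highest rises. Saa1 (ENSMUSG00000074115, GRCm38 chromosome 7, 46740497 to 46742980) went from 31.1 ± 13.1 CPM in control to 910.3 ± 655 CPM in MTX, a 29.3-fold difference (log2 4.87 ± 0.51, adjusted p = 0.000217). Saa2 (chromosome 7, 46751790 to 46754313) rose 77-fold, from 7.04 ± 2.59 to 542 ± 495 CPM (adjusted p = 0.000235), and reads of these near-identical genes may be split between them. Lcn2, encoding the iron-sequestering lipocalin 2 (chromosome 2, 32384633 to 32388252), rose 29-fold, Orm2 10.3-fold and haptoglobin (Hp) 2.71-fold, from 2096 ± 320 to 5676 ± 1417 CPM. Of 28 acute phase genes tested, 16 rose, and 23 rose when adjusted over the list alone (camera adjusted p = 3.64e-19, adjusted p = 0.342 with an estimated correlation). Every MTX library lay above every control library for Saa1, Saa2, Lcn2, Orm2 and Hp.

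**Figure D1:**
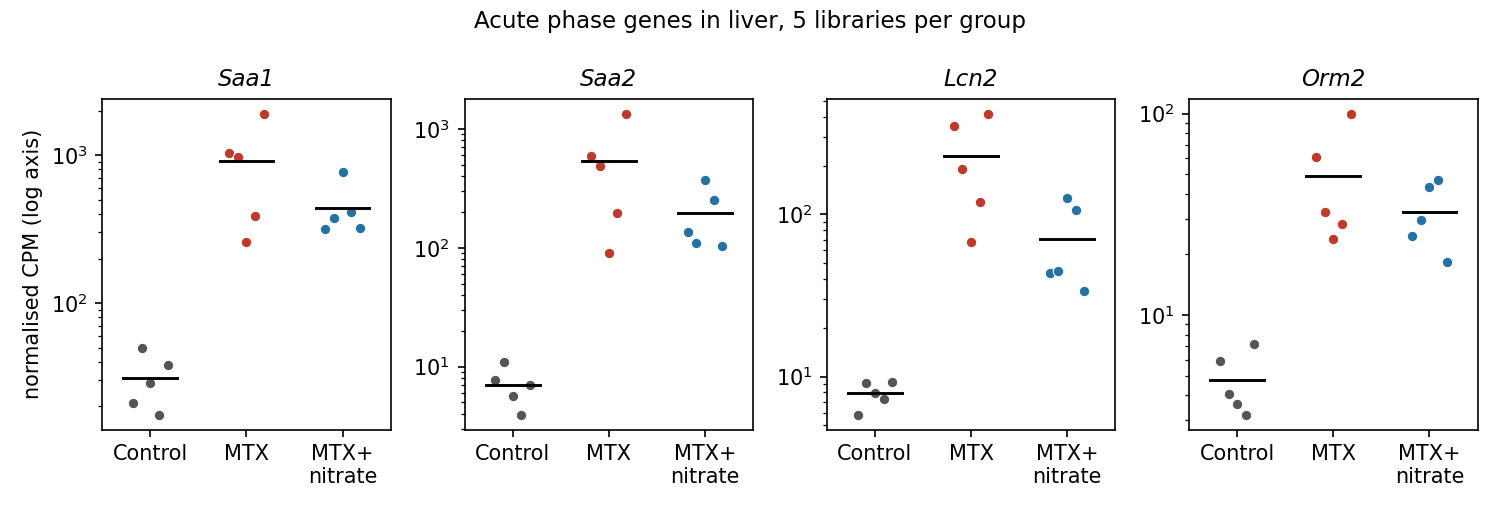
Expression of Saa1, Saa2, Lcn2 and Orm2 in CPM on a log axis, with 1 point per library and a black line at the mean of each group of 5. All MTX libraries lay above all control libraries for each gene, and the MTX+nitrate means (439, 195, 70.8 and 32.5 CPM) lay between the MTX and control means. This is the order of the means only, and no test of MTX+nitrate against MTX is given here for these genes.

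Among NF-κB and cytokine genes, 3 of 22 rose with MTX, and 3 when adjusted over the list alone (camera adjusted p = 0.0167, adjusted p = 0.584 with an estimated correlation). They were the monocyte attractant Ccl2 (0.387 ± 0.274 to 5.95 ± 5.4 CPM), the cytokine Il1b (1.1 ± 0.453 to 3.98 ± 2.48 CPM) and the lipopolysaccharide co-receptor Cd14 (4.91 ± 1.38 to 17.1 ± 11 CPM). Without MTX library 1 or 5, the list's adjusted p was 0.105 or 0.164. The monocyte and dendritic cell list had 2 of 11 genes higher, and 5 when adjusted over the list alone (camera adjusted p = 0.02, adjusted p = 0.545 with an estimated correlation, 0.135 without MTX library 5). These were Itgax (0.531 ± 0.202 to 2.52 ± 1.48 CPM) and F13a1 (0.31 ± 0.219 to 3.92 ± 4.17 CPM). Heat shock genes, whose products refold damaged proteins, had 4 of 17 members higher and 5 when adjusted over the list alone (camera adjusted p = 0.000326, adjusted p = 0.545 with an estimated correlation). Hspa1a rose 3.81-fold, Hspa1b 3.3-fold, Bag3 2.18-fold and Dnajb1 2.09-fold, and the first 2 share most of their sequence. The matrix genes Thbs1 (2.24 ± 0.708 to 21.2 ± 15.5 CPM, 9.42-fold) and Ctgf (3.98 ± 1.22 to 14.7 ± 8.6 CPM, 3.69-fold) also led the rises, as did a further serum amyloid gene, Saa3 (5.38-fold).

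Of 25 cholesterol synthesis genes, 11 were higher with MTX and 16 when adjusted over the list alone (camera adjusted p = 4.84e-12, adjusted p = 0.46 with an estimated correlation). Nsdhl, a sterol-4-demethylation enzyme, rose 1.81-fold (63.8 ± 15.5 to 115.8 ± 16.4 CPM), mevalonate kinase (Mvk) 1.83-fold, Acat2 1.72-fold and the lanosterol demethylase Cyp51 1.74-fold, the last overlapping Akap9 on the other strand. Xenobiotic metabolism genes had 3 of 22 higher and 1 lower (6 and 1 when adjusted over the list alone, camera adjusted p = 0.00524, adjusted p = 0.431 with an estimated correlation, 0.0613 without MTX library 5). Cyp2c29 rose 2.26-fold, from 1819 ± 521 to 4116 ± 610 CPM (adjusted p = 0.00414). Cyp2b10 rose 3.73-fold and Alas1, the first enzyme of haem synthesis, 3.56-fold, while the carboxylesterase Ces2c fell 2.06-fold. Pericentral genes, expressed by hepatocytes around the central vein, had 3 of 20 higher and 6 when adjusted over the list alone (camera adjusted p = 0.00422, adjusted p = 0.484 with an estimated correlation). These 3, Cyp2c50 (1.4-fold), Cyp2c54 (1.6-fold) and Aldh1a1 (1.55-fold), include near-identical cytochrome P450 paralogs. Tyms, the thymidylate synthase gene on the folate list, was at 5.11 ± 1.33 and 7.16 ± 1.46 CPM (adjusted p = 0.138).

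Oxidant defence enzymes had 3 of 16 members higher with MTX, Prdx2 (1.24-fold), Sod1 (1.21-fold) and Glrx (1.24-fold), with 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000731, adjusted p = 0.431 with an estimated correlation). Targets of NRF2, a transcription factor activated by oxidants, had 2 of 25 higher over all genes and over the list alone: the peroxidase Prdx1 (666.6 ± 53.2 to 928 ± 87.3 CPM, 1.39-fold, adjusted p = 0.00883) and the ferritin chain Fth1 (1.21-fold). The NRF2 list (camera adjusted p = 0.0437, adjusted p = 0.484 with an estimated correlation) had an adjusted p of 0.102 without control library 1, 0.114 without control library 4, 0.148 without MTX library 3 and 0.0552 without MTX library 5. It had 0.212 after correction for transcript length and GC content. The Prdx2, Sod1, Glrx and Fth1 calls held in 2, 1, 2 and 1 of the 10 fits that left out 1 library, and all were lost without an expression filter and in a fit over 2 groups, with highest adjusted p-values over all settings of 0.0823, 0.135, 0.112 and 0.132. Those of Prdx2 and Fth1 were also lost after the correction, while Prdx1 stayed called throughout.

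Genes that fell with MTX included the clock genes Dbp, Nr1d2 and Tef and the Wnt pathway genes Fzd6 and Rspo1. Dbp, an output transcription factor of the circadian clock, fell 20.6-fold (27.7 ± 33.3 to 1.33 ± 2.09 CPM), although the more abundant Sphk2 overlaps it on the other strand. Its log2 change, -4.36, was -3.33 without control library 1 (adjusted p = 0.0513) and -6.11 without MTX library 3, and its call was also lost without MTX library 1 or 2 (adjusted p = 0.0548 and 0.0537). Nr1d2 fell 2.61-fold and Tef 2.77-fold, both calls being lost without control library 1, 3 or 4 or MTX library 1, 2 or 4 (adjusted p up to 0.0815 and 0.0878) and in a fit over 2 groups. Per3 fell by 2.07 on the log2 scale (adjusted p = 0.033, chosen after its values were seen). It was at 38.9 CPM in control library 1 and at 5.56 to 9.4 CPM in the other controls, so the size of its fall rests in part on that library. Nfil3, a repressor that acts against Dbp, rose 2.8-fold (24.8 ± 7.44 to 69.2 ± 15.9 CPM, adjusted p = 0.00276). Of 16 clock genes 1 was higher and 4 lower, or 4 and 6 when adjusted over the list alone, and the list test, which asks for 1 direction, gave an adjusted p of 0.192. Of 26 cell cycle genes, Top2a fell, 1 over all genes and over the list alone, from 2.95 ± 1.38 to 1.21 ± 0.353 CPM (camera adjusted p = 0.0212, adjusted p = 0.584 with an estimated correlation, 0.212 without control library 2). The Top2a call held in 2 of the 10 fits that left out 1 library, with adjusted p-values up to 0.0952, and was lost without an expression filter, after the length and GC correction, in a fit over 2 groups and with limma-voom. The Wnt receptor Fzd6 (ENSMUSG00000022297, chromosome 15, 39006034 to 39038188) fell 2.57-fold, from 11 ± 2.17 to 4.29 ± 1.21 CPM (adjusted p = 0.00686). The secreted Wnt enhancer Rspo1, with Fzd6 the 2 Wnt pathway components called of 28, over all genes and over the list alone, went from 1.62 ± 1.27 to 0.0611 ± 0.061 CPM (adjusted p = 0.0231). Its call was lost without control library 1 or MTX library 1 or 2 (adjusted p = 0.0549, 0.0596 and 0.0642) and with limma-voom (0.11). Wnt/β-catenin target genes were lower as a list of 15 (camera adjusted p = 0.0331, adjusted p = 0.431 with an estimated correlation), with 3 lower when adjusted over the list alone and no member past the threshold over all genes. Without control library 5, MTX library 1 or MTX library 5 this list had an adjusted p of 0.0784, 0.0868 or 0.0613. Its lowest p-values were those of Nkd1 (6.21 ± 0.781 to 4.37 ± 0.442 CPM, adjusted p = 0.0614) and Sp5 (2.35 ± 0.737 to 0.833 ± 0.47 CPM, adjusted p = 0.0659). Axin2, a feedback target of the pathway, was at 8.98 ± 3.48 and 5.38 ± 1.29 CPM (adjusted p = 0.102), and β-catenin itself (Ctnnb1) at 241.8 ± 16 and 253 ± 10.9 CPM (adjusted p = 0.594). Markers of sinusoidal endothelial cells, which line the liver's capillaries, were also lower as a list of 16 (camera adjusted p = 0.000326, adjusted p = 0.545 with an estimated correlation), with 5 lower when adjusted over the list alone, led by Oit3 (22.1 ± 2.77 to 15.4 ± 2.73 CPM, adjusted p = 0.0546) and Flt4 (29.2 ± 5.8 to 20.3 ± 2.85 CPM, adjusted p = 0.0707).

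Further falls were those of Gpcpd1 (3.04-fold), Cables1 (2.95-fold), Zc3h12d (2.59-fold) and the integrin Itga8 (2.59-fold, 23.3 ± 6.4 to 9 ± 3.22 CPM). Immediate early genes and Kupffer cell markers were higher as lists of 19 and 15 with no member past the threshold over all genes, and with 1 and 2 when adjusted over the list alone (camera adjusted p = 0.0308 and 0.0431, adjusted p = 0.584 and 0.63 with an estimated correlation). Their adjusted p was 0.124 and 0.194 after the length and GC correction. The immediate early call was lost without control library 3, MTX 1 or MTX 5 (adjusted p = 0.0679, 0.105 and 0.167). The Kupffer call was lost without control library 3 or 4, or MTX 1, 4 or 5 (adjusted p = 0.202, 0.202, 0.0992, 0.107 and 0.135). Ier5 (adjusted p = 0.0524), Jund (0.113), Marco (0.0644) and Cd68 (0.0779) had the lowest p-values in them. Among p53 targets, the cell cycle inhibitor Cdkn1a was at 7.29 ± 5.89 and 25.9 ± 13.1 CPM (adjusted p = 0.0501) and Bax at 13.9 ± 2.8 and 18.4 ± 2.29 CPM (adjusted p = 0.102). The lists that did not pass had adjusted p-values from 0.0573 (Wnt pathway components and mitochondrially encoded genes) to 0.948 (nitric oxide and nitrate handling). Between these lay fasting, erythroid, female- and male-biased, clock, p53, B cell, folate, integrated stress response, T and NK cell, cholangiocyte, purine and pyrimidine, apoptosis, interferon, periportal, fatty acid oxidation, bile acid, stellate and lipogenesis genes. For fatty acid oxidation and lipogenesis the list test pointed down while the median and mean fold change were above 0. Their called members, chosen after their values were seen, were Tat, Tsc22d3, Irs2, Atf4, Dnajb9, Endog, Adh5, Arg2, Il7r and Sox9, all higher, besides Spp1, described further below. Neutrophil, adipocyte, pancreatic and muscle markers had 4, 2, 2 and 1 members tested, too few for the list test, and Mmp9 (adjusted p = 0.0727) and Csf3r (0.0833) led the first, with 2 higher when adjusted over the list alone.

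By edgeR's quasi-likelihood test, 521 of 14219 genes differed between MTX and control, 293 higher and 228 lower, and 133 of them by at least 1 on the log2 scale. Groups did not overlap for 5.42% of genes, against 0.794% by chance. After correction for transcript length and GC content, 363 genes were called, 111 of them lower, and called genes that were higher had a median transcript length of 1969 bases against 5020.5 for those lower. The lists past the threshold numbered 14 of 36, 0 with an estimated correlation, and 10 of 100 splits of the 10 libraries, the real one included, called as many, so their number was not beyond chance. The gene count rested on single libraries, at 112, 192, 248 and 250 genes without control library 1, 3, 4 or 5, at 89, 86 and 237 without MTX library 1, 2 or 4, and at 995 without MTX library 5. Of the 54 called genes named for this comparison, 23 stayed called in all 10 such fits, Saa1, Saa2, Lcn2, Orm2, Hp, Thbs1, Hspa1a, Ctgf, Nsdhl, Cyp2c29, Prdx1, Nfil3, Fzd6 and Itga8 among them, while Top2a, Aldh1a1, Fth1, Prdx2, Sod1, Glrx, Cd14, Cyp2b10, Ces2c and F13a1 stayed called in at most 2. Cyp2c54, Cables1, Saa3, Cyp2c50, Nr1d2, Alas1, Tef, Cyp51 and Il1b did so in 3 to 5. Without MTX library 5 the log2 change of Saa2 went from 6.27 to 5.6 and that of F13a1 from 3.63 to 2.85 (adjusted p = 0.0822).

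The second comparison asked what nitrate changed in MTX-treated livers. Noct, Per1 and Cyp7a1 were among the leading rises. Noct, a rhythmic regulator of lipid metabolism (ENSMUSG00000023087, chromosome 3, 51224447 to 51251644), went from 3.75 ± 2.27 CPM in MTX to 27.9 ± 7.77 CPM in MTX+nitrate, 7.41-fold higher (log2 2.89 ± 0.39, adjusted p = 0.00304), and stood at 2.3 ± 1.31 CPM in control. The clock gene Per1 (chromosome 11, 69095217 to 69109960) rose 6.42-fold, from 4.36 ± 2.57 to 28.1 ± 8.17 CPM (adjusted p = 0.0151). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275633), rose 4.27-fold, from 33.6 ± 6.68 to 144 ± 47.9 CPM (adjusted p = 0.00578). The kinase Sik1 rose 3.8-fold, Rasgef1b 3.48-fold (12.8 ± 1.68 to 44.4 ± 15 CPM, adjusted p = 9.87e-05) and the ubiquitin ligase Ube2ql1 4.67-fold. These 6 calls held in each fit that left out 1 library, and all MTX+nitrate libraries lay above all MTX libraries for them. Papln (3.91-fold) and the vascular matrix gene Svep1 (3.63-fold) were the other leading rises.

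**Figure D2:**
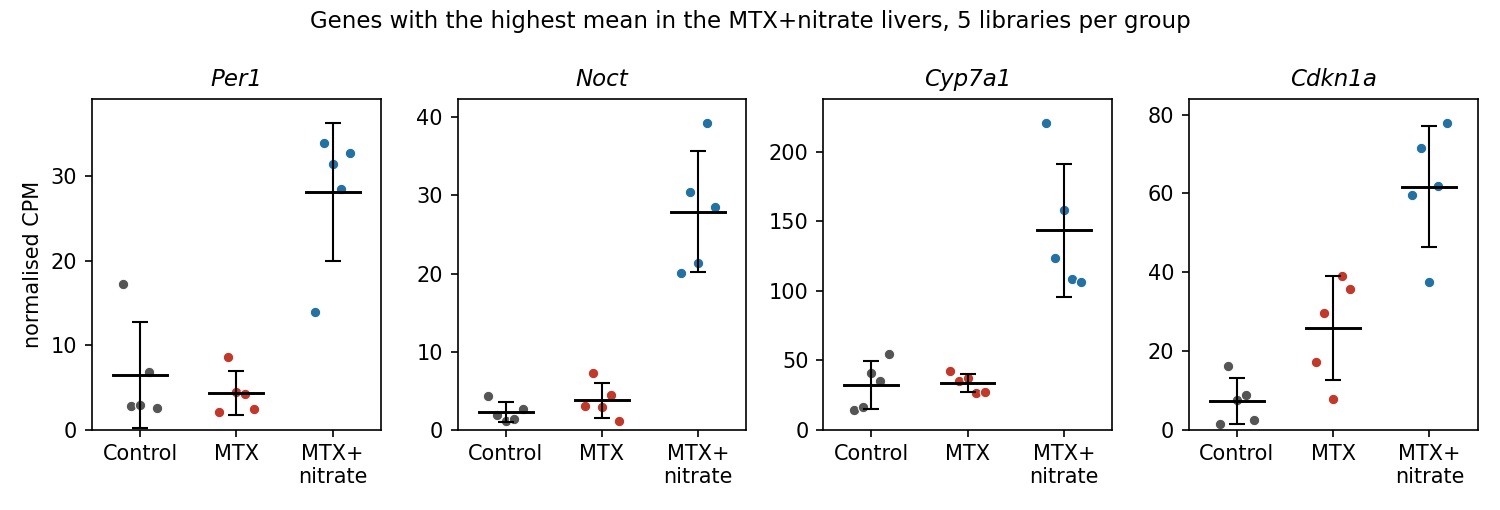
Expression of Per1, Noct, Cyp7a1 and Cdkn1a in CPM from 0, with 1 point per library, a black line at the mean and bars of 1 SD for each group of 5. MTX+nitrate means were 28.1, 27.9, 144 and 61.7 CPM, against 4.36, 3.75, 33.6 and 25.9 CPM in MTX, and the difference from MTX passed the test for all but Cdkn1a (adjusted p = 0.129).

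Gluconeogenesis and fasting genes had 5 of 20 members higher, and 8 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.000413, adjusted p = 0.256 with an estimated correlation). Besides Per1 and Sik1 these were the transcription factors Foxo1 (35.4 ± 5.03 to 59.6 ± 14 CPM, 1.68-fold) and Cebpb (97.9 ± 21.3 to 161 ± 27.5 CPM, 1.65-fold), and Tsc22d3, a glucocorticoid-induced gene chosen after its values were seen (log2 1.02, adjusted p = 0.0278). All 5 were still called after correction for transcript length and GC content, at adjusted p-values from 0.0294 to 0.0457. The p53 target Trp53inp1 rose 1.7-fold (adjusted p = 0.025), and Cdkn1a was at 25.9 ± 13.1 and 61.7 ± 15.4 CPM (adjusted p = 0.129).

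Acute phase genes had 8 of 28 members lower with nitrate and 17 when adjusted over the list alone (camera adjusted p = 3.15e-07, adjusted p = 0.299 with an estimated correlation). Serpina3m fell 1.46-fold (619 ± 74.6 to 425 ± 60.2 CPM, adjusted p = 0.0221), the interleukin-1 antagonist Il1rn 5.41-fold (10.3 ± 7.65 to 1.89 ± 0.989 CPM), Crp 1.34-fold and ceruloplasmin (Cp) 1.33-fold. Serpina3m overlaps the far more abundant Serpina3k, so its counts are uncertain. Spp1, which encodes the secreted protein osteopontin and marks cholangiocytes, fell 3.7-fold, from 136.6 ± 79.9 to 36.9 ± 1.81 CPM (adjusted p = 0.00934), close to its control level of 43.3 ± 10.4 CPM. The neutrophil marker Mmp9 went from 2.75 ± 2.69 to 0.283 ± 0.175 CPM (adjusted p = 0.025), S100a8 from 1.29 ± 1.19 to 0.16 ± 0.041 CPM (adjusted p = 0.0395) and the monocyte marker Chil3 from 3.04 ± 2.2 to 0.303 ± 0.439 CPM (adjusted p = 0.0393). The 4 neutrophil markers tested were all lower when adjusted over the list alone, and 2 over all genes. The monocyte list had 1 of 11 lower, 4 when adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.517 with an estimated correlation), and lost its call without MTX library 1 or 5 or MTX+nitrate library 2 (adjusted p = 0.076, 0.149 and 0.0556) and after the length and GC correction (0.103). In the NF-κB list (camera adjusted p = 0.0649), 2 of 22 were lower, Ccl2 and Cxcl1, both chosen after their values were seen, and 3 when adjusted over the list alone.

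Oxidant defence enzymes had 5 of 16 members lower with nitrate, and 9 lower and 1 higher when adjusted over the list alone (camera adjusted p = 3.24e-05, adjusted p = 0.256 with an estimated correlation). They were Glrx (1.32-fold), the glutathione peroxidases Gpx4 (1.43-fold) and Gpx1 (1.33-fold), the selenium carrier Selenop (1.26-fold) and Sod1, the last chosen after its values were seen. NRF2 targets had 4 of 25 lower over all genes and over the list alone (camera adjusted p = 0.00345, adjusted p = 0.256 with an estimated correlation): Prdx1 (928 ± 87.3 to 649 ± 31.5 CPM, 1.43-fold, adjusted p = 0.00699), Txn1 (1.28-fold), Osgin1 (1.69-fold) and Fth1 (1.21-fold). Xenobiotic metabolism genes had 5 of 22 lower and 9 when adjusted over the list alone (camera adjusted p = 0.000145, adjusted p = 0.256 with an estimated correlation). Cyp3a11, a major drug-oxidising enzyme, fell 1.62-fold (4971 ± 609.5 to 3061 ± 648 CPM, adjusted p = 0.0209), Cyp2c29 1.7-fold, Ugt2b34 1.31-fold and Ces2a 1.33-fold, and Cyp3a25, chosen after its values were seen, was the fifth. Pericentral genes had 3 of 20 lower and 5 when adjusted over the list alone (camera adjusted p = 0.000169, adjusted p = 0.269 with an estimated correlation): Rgn (1.26-fold), Lect2 (1.33-fold) and Cyp2c50 (1.35-fold). The integrated stress and unfolded protein response had 2 of 24 lower, Ero1lb (1.51-fold) and Xbp1 (1.39-fold), and 6 when adjusted over the list alone (camera adjusted p = 3.4e-05, adjusted p = 0.299 with an estimated correlation). Fatty acid oxidation genes had 1 of 29 lower, Creb3l3 (1.3-fold), and 2 when adjusted over the list alone (camera adjusted p = 4.27e-05, adjusted p = 0.406 with an estimated correlation). Mitochondrially encoded genes had 2 of 13 lower, mt-Atp6 (2.46-fold) and mt-Nd2 (1.47-fold), and 8 when adjusted over the list alone (camera adjusted p = 2.25e-05, adjusted p = 0.269 with an estimated correlation, 0.124 after the length and GC correction). Counts of mt-Atp6 and of the tRNA gene mt-Tl2 (2.79-fold lower) depend on how reads of adjoining mitochondrial genes were assigned. Heat shock genes were lower as a list of 17 with no member past the threshold over all genes or over the list alone (camera adjusted p = 2.79e-05, adjusted p = 0.417 with an estimated correlation), led by Hspe1 (121 ± 25 to 92.5 ± 11.7 CPM, adjusted p = 0.086) and Hsp90aa1 (adjusted p = 0.137).

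Wnt target genes, named in the study's title, were higher with nitrate as a list. All 15 had a positive fold change, with a median of 0.45 on the log2 scale (camera adjusted p = 0.000731, adjusted p = 0.256 with an estimated correlation). Of these, Nkd1, a feedback inhibitor of the pathway (ENSMUSG00000031661, chromosome 8, 88521354 to 88594884), passed the test (4.37 ± 0.442 to 6.7 ± 1.04 CPM, 1.53-fold, adjusted p = 0.0302), and 2 did when adjusted over the list alone. Axin2 was at 5.38 ± 1.29 and 9.58 ± 2.28 CPM (adjusted p = 0.0677). Ctnnb1 was at 253 ± 10.9 and 251 ± 4.97 CPM (adjusted p = 0.933), Lgr5 at 3.87 ± 0.931 and 4.14 ± 1.68 (0.889), glutamine synthetase (Glul) at 546 ± 32.8 and 438 ± 135 (0.229), Ccnd1 at 17.9 ± 7.62 and 33 ± 20.4 (0.153) and Myc at 8 ± 6.78 and 16.8 ± 23 (0.349). Wnt pathway components (camera adjusted p = 0.0644) had 2 of 28 higher over all genes and over the list alone. These were Fzd6 (4.29 ± 1.21 to 8.76 ± 2.59 CPM, 2.04-fold, adjusted p = 0.0245) and Rspo1, which was at 1.17 ± 0.985 CPM (adjusted p = 0.0311) and was not called without MTX library 1, 2, 3 or 4 or MTX+nitrate library 1 or 3 (0.0691, 0.0722, 0.064, 0.0507, 0.0725 and 0.0563) or with limma-voom (0.106). All 16 sinusoidal endothelial markers had a positive fold change, 5 rose, and 13 when adjusted over the list alone (camera adjusted p = 1.97e-08, adjusted p = 0.269 with an estimated correlation). They were Eng (1.44-fold, overlapping Fpgs), Flt4 (1.66-fold), Oit3 (1.58-fold), Kdr (1.67-fold) and Stab1, the last chosen after its values were seen.

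**Figure D3:**
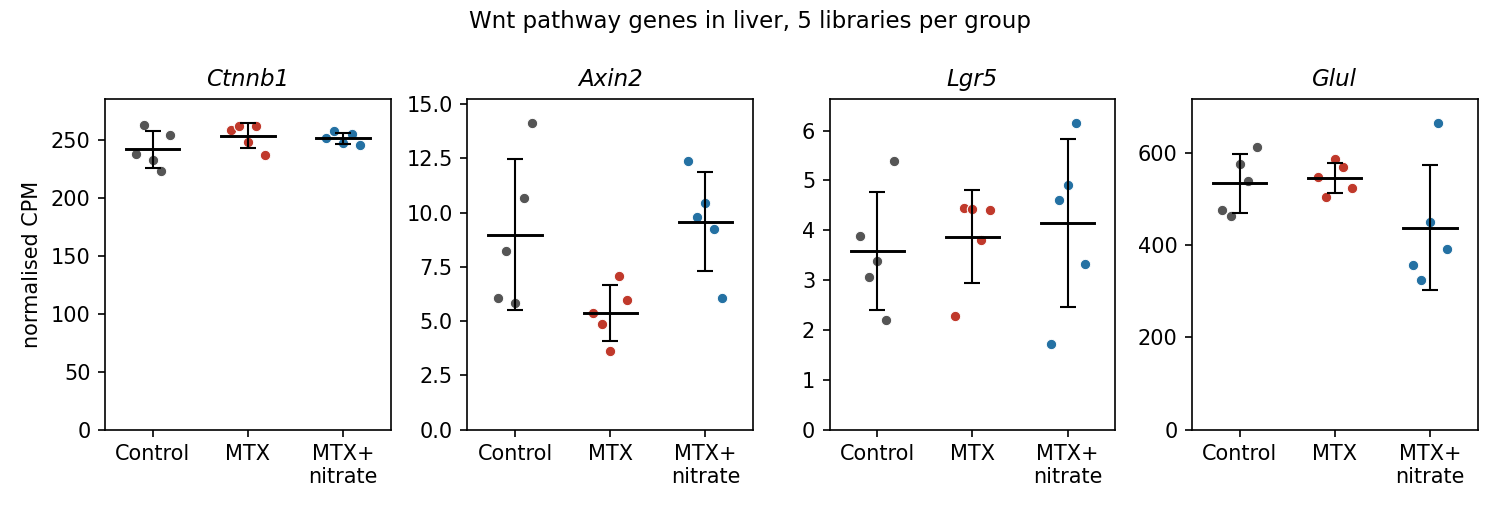
Expression of Ctnnb1, Axin2, Lgr5 and Glul in CPM from 0, with 1 point per library, a black line at the mean and bars of 1 SD for each group of 5. No difference between groups passed the test for these genes, with Axin2 in MTX+nitrate against MTX closest (9.58 against 5.38 CPM, adjusted p = 0.0677).

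Among the other leading falls were Zbtb16 (2.28-fold), the RNA-editing enzyme Apobec1 (2.01-fold), Ugt2b38 (1.86-fold), Efna1 (1.85-fold), Banp (1.82-fold) and Clec2d (1.78-fold). Lipogenesis genes (higher) and Kupffer cell markers (lower) passed as lists of 19 and 15 with no member past the threshold over all genes or over the list alone (camera adjusted p = 0.0276 and 0.0434, adjusted p = 0.717 with an estimated correlation for both). Their adjusted p was 0.0915 and 0.198 after the length and GC correction. The lipogenesis call, led by Mlxipl (adjusted p = 0.0555) and Fasn (0.262), was lost without MTX library 1 or 5 or MTX+nitrate library 4 or 5 (adjusted p = 0.0792, 0.22, 0.18 and 0.164). The Kupffer call, led by Cd68 (adjusted p = 0.0818) and Cd163 (0.204), was lost without MTX library 1, 4 or 5 or MTX+nitrate library 1 or 5 (adjusted p = 0.135, 0.11, 0.103, 0.125 and 0.269). The remaining lists reached adjusted p-values from 0.273 (cholangiocyte) to 0.986 (purine and pyrimidine synthesis). Between these lay erythroid, bile acid, B cell, periportal, apoptosis, p53, female- and male-biased, cholesterol, cell cycle, folate, nitric oxide, stellate, T and NK cell, immediate early, interferon and clock genes. Median, mean and test differed in sign for folate, purine, cholesterol, clock, sex-biased and T and NK cell lists. In the folate list Bhmt (adjusted p = 0.0854) and Tyms (0.129) came first. In the clock list Bhlhe40 (adjusted p = 0.072) and Nr1d1 (0.134) came first. Klf2, higher, and Endog and Cycs, lower, were the further called members, chosen after their values were seen.

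In all, 613 of 14219 genes differed between MTX+nitrate and MTX, 337 higher and 276 lower, and 99 by at least 1 on the log2 scale. Groups did not overlap for 6.26% of genes. After the length and GC correction 96 were higher and 198 lower, and called genes that were higher had a median transcript length of 4671 bases against 1733 for those lower. The correction ended 23 of the 61 named calls, among them Nkd1, Eng, Flt4, Kdr, Gpx1, Selenop, Txn1, Crp, Cyp2c29, Rgn, Lect2, mt-Atp6, mt-Nd2, Chil3 and S100a8, and kept those of Noct, Per1, Cyp7a1, Sik1, Foxo1, Cebpb, Prdx1, Spp1, Serpina3m and Cyp3a11. The lists past the threshold numbered 15 of 36, 0 with an estimated correlation, and 13 of 100 splits of the 10 libraries, the real one included, called as many. The gene count was 166, 219, 341 and 371 without MTX library 1, 2, 3 or 4, and 280, 184, 285 and 325 without MTX+nitrate library 1, 2, 3 or 4, and 22 named calls held in all 10 such fits, while those of Cyp2c50, Fth1, Selenop, Creb3l3, mt-Atp6 and S100a8 held in at most 2. Those of mt-Nd2, Lect2, Xbp1, Chil3, Cyp2c29, Kdr, Banp, Nkd1, Rspo1, Ugt2b38, Efna1, Ugt2b34 and Ces2a held in 3 to 5. The log2 changes of Mmp9 and S100a8 went from -3.24 to -2.52 and from -2.96 to -2.29 without MTX library 1 (adjusted p = 0.067 and 0.106), that of Rspo1 from 4.14 to 3.54 without MTX+nitrate library 1 (0.0725) and that of Chil3 from -3.26 to -4.72 without MTX+nitrate library 3.

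The third comparison asked how livers given both nitrate and MTX differed from control. Acute phase, fasting and cholesterol synthesis genes were higher as lists. Saa2 was 27.7-fold higher (195 ± 116 CPM), Saa1 14.1-fold (439 ± 187 CPM, log2 3.82 ± 0.48, adjusted p = 0.000865), Lcn2 8.95-fold and Orm2 6.8-fold. Of 28 acute phase genes, 6 rose and 7 when adjusted over the list alone (camera adjusted p = 2.19e-06, adjusted p = 0.799 with an estimated correlation). Noct rose 12.1-fold and Ctgf 8.77-fold. Cdkn1a, the p53-induced cell cycle inhibitor (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), rose 8.44-fold, from 7.29 ± 5.89 to 61.7 ± 15.4 CPM (log2 3.08 ± 0.51, adjusted p = 0.00669). With Trp53inp1 (1.73-fold) it made 2 of 26 p53 targets higher, and 3 when adjusted over the list alone (camera adjusted p = 0.0406, adjusted p = 0.799 with an estimated correlation). That list's adjusted p was 0.0659, 0.0627, 0.236 and 0.0746 without control library 1 or 4 or MTX+nitrate library 1 or 3.

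Fasting genes had 6 of 20 members higher, and 12 higher and 1 lower when adjusted over the list alone (camera adjusted p = 7.51e-07, adjusted p = 0.202 with an estimated correlation). Tsc22d3 rose 4.28-fold (40.8 ± 9.13 to 174.9 ± 33.6 CPM, adjusted p = 0.000418), tyrosine aminotransferase (Tat) 3.78-fold (541.9 ± 171 to 2049 ± 644.5 CPM), Sik1 5.58-fold and Klf15 1.75-fold. Tsc22d3 stood at 86.4 ± 34.4 CPM in MTX. Cholesterol synthesis genes had 4 of 25 higher, among them Mvk (1.71-fold), Acat2 (1.57-fold) and Dhcr7 (1.7-fold), and 19 when adjusted over the list alone (camera adjusted p = 2.2e-11, adjusted p = 0.799 with an estimated correlation). Fatty acid oxidation genes had 3 of 29 lower and 6 when adjusted over the list alone (camera adjusted p = 8.48e-06, adjusted p = 0.799 with an estimated correlation). These were Creb3l3 (1.4-fold), the lipid droplet gene Plin2 (2.04-fold) and Cpt1a (1.71-fold), which admits fatty acids to mitochondria. Cyp7a1, chosen here after its values were seen, was higher by 2.16 on the log2 scale (32.2 ± 17.1 to 144 ± 47.9 CPM, adjusted p = 0.00294).

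Clock genes went both ways. Dbp fell 43.3-fold (27.7 ± 33.3 to 0.626 ± 0.402 CPM), the repressors Nr1d1 5.95-fold (132 ± 29.1 to 22.2 ± 11.6 CPM) and Nr1d2 3.5-fold, Per3 4.32-fold and Tef 2.81-fold, while Nfil3 rose 2.05-fold. Of 16 clock genes 2 were higher and 5 lower, or 3 and 6 when adjusted over the list alone, and the list test, which asks for 1 direction, gave an adjusted p of 0.412. Per3 was at 38.9 CPM in control library 1 and at 5.56 to 9.4 CPM in the other controls, and Per3, Tef and Nr1d1 lost their calls without that library (adjusted p = 0.0967, 0.103 and 0.0696). The log2 changes of Dbp and Per3 then went from -5.44 to -4.4 and from -2.11 to -1.23. The arrestin-like gene Arrdc3 fell 8.66-fold (568 ± 99.5 to 65.6 ± 26.6 CPM, adjusted p = 0.00136), Slc25a34 3.22-fold and mt-Tl2 2.7-fold.

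The stress response list had Atf4 higher (1.42-fold) and Ero1lb (1.55-fold), Creld2 (2.95-fold) and Hsp90b1 (1.6-fold) lower of 24, and 1 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.00398, adjusted p = 0.885 with an estimated correlation, 0.0552 without MTX+nitrate library 3). Immediate early genes had 1 of 19 higher, Klf2 (2.4-fold), and 3 when adjusted over the list alone (camera adjusted p = 0.0435). Male-biased genes (lower, camera adjusted p = 0.0406), mitochondrially encoded genes (lower, 0.0172) and endothelial markers (higher, 0.0399) passed as lists of 16, 13 and 16 with no member past the threshold over all genes, and with 1 in all, Gpr182, when adjusted over the list alone. Their lowest adjusted p-values were those of Nudt7 (0.0932) and Mup1 (0.218), mt-Co1 (0.149) and mt-Nd1 (0.202), and Gpr182 (0.0566) and Stab1 (0.113). Each of these 4 lists had an adjusted p of 0.885 with an estimated correlation, and of 0.135, 0.128, 0.997 and 0.128 after the length and GC correction. Leaving out control library 1, 3, 4 or 5 or MTX+nitrate library 1, 3 or 4 ended the immediate early call (adjusted p = 0.0659, 0.133, 0.0627, 0.0725, 0.245, 0.0985 and 0.088). Control 1, 3 or 5 or MTX+nitrate 3 or 4 ended the male-biased call (0.0659, 0.108, 0.188, 0.456 and 0.169). Control 1 or 2 or MTX+nitrate 3 ended the mitochondrial call (0.0659, 0.181 and 0.0985), and control 2, 3 or 4 or MTX+nitrate 3 or 4 the endothelial one (0.27, 0.111, 0.0528, 0.269 and 0.109). Wnt target genes had no member called (camera adjusted p = 0.487), with Notum (21.3 ± 3.08 to 30.3 ± 6.62 CPM, adjusted p = 0.0811) and Myc (0.0829) first, 2 higher when adjusted over the list alone, Axin2 at 8.98 ± 3.48 and 9.58 ± 2.28 CPM (0.884) and Ctnnb1 at 241.8 ± 16 and 251 ± 4.97 CPM (0.739). All other lists lay between adjusted p-values of 0.0565 (lipogenesis) and 0.894 (Kupffer cell). These were cell cycle, apoptosis, bile acid, NRF2, oxidant defence, xenobiotic, purine, T and NK cell, periportal, interferon, female-biased, stellate, NF-κB, pericentral, nitric oxide, cholangiocyte, folate, heat shock, monocyte, B cell, Wnt component and erythroid genes, and median, mean and test differed in sign for heat shock, interferon, xenobiotic, pericentral and B cell lists. Called members among them, chosen after their values were seen, were Acss2 and Alas1, higher, and Cyp3a25, Ces2c, Slc1a2 and Osgin1, lower. Of the fixed genes, Cdkn1a passed here and in no other comparison, and Tyms, the nitrate transporter gene Slc17a5, Bax, Bcl2, Ctnnb1, Axin2, Ccnd1, Myc, Cyp2e1, Lgr5 and Glul, did not pass in any.

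In all, 342 of 14219 genes differed between MTX+nitrate and control, 201 higher and 141 lower, and 114 by at least 1 on the log2 scale. Groups did not overlap for 5.2% of genes. After the length and GC correction 103 were higher and 117 lower, and the lists past the threshold, 10 of 36 and 0 with an estimated correlation, were as many in 30 of 100 splits of the 10 libraries, the real one included. The gene count was 99, 130, 187 and 139 without control library 1, 3, 4 or 5, and 141, 174, 132 and 146 without MTX+nitrate library 2, 3, 4 or 5, and the list count was 4 without MTX+nitrate library 3. In all 10 such fits 16 of the 34 named calls held, among them Saa1, Noct, Ctgf, Cdkn1a, Sik1, Tsc22d3, Tat, Nfil3, Dbp, Nr1d2 and Arrdc3, while those of Tef, Creld2, Hsp90b1, Cpt1a and Dhcr7 held in at most 2, and those of Per3, Acat2, Mvk, Plin2, Trp53inp1 and Klf15 in 3 to 5.

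The last question was how far nitrate moved MTX-responsive genes back towards control. Of the 521 genes called for MTX, 480 (92.1%) moved the other way with nitrate. Because both comparisons share the MTX libraries, this share was 70.3% over the 1492 genes called on average in 20 simulations with the MTX effect and no nitrate effect. It was 82.6 ± 12.5% when the MTX libraries were split between the comparisons, over 146.4 called genes on average. The simulations drew genes independently from the fitted group means, whose sampling noise adds to the MTX effect, and called more genes than the data. Their share is therefore not the chance level for the observed 92.1%. Past both thresholds in opposite directions were 141 genes, 75 first higher and 66 first lower, while 2 were called in the same direction. Independent lists would give 5.69 and 5.4. Simulations, which left out the nitrate effect, gave 0, and the split MTX libraries, with both effects kept but smaller MTX groups, gave 2.55 on average. The excess of the 141 over these values is therefore not a measure of the nitrate effect. The covariance of the fold changes was -0.115, against -0.0424 in simulations and -0.0734 with split libraries, and their correlation across genes was -0.581 against -0.27. Among these genes, Rps3, a ribosomal protein gene with many processed copies, went from 238 ± 18.1 CPM in control to 335 ± 25.4 in MTX and 233 ± 19.5 in MTX+nitrate. The secreted C1qtnf1 went from 13.3 ± 1.34 to 7.27 ± 1.24 and 13.5 ± 2.05 CPM, Nav2 from 63.4 ± 5.71 to 35.5 ± 2.7 and 65.8 ± 17.6 CPM, and Plekha6 from 99.3 ± 9.94 to 59.3 ± 7.15 and 93.8 ± 14.2 CPM. Leng8, Plekhg1, the histone demethylase gene Kdm3b, the pseudogene Gm6136, Prdx1 and Spp1 completed the 10 with the clearest pattern. The count of 141 was 17, 21, 69 and 227 without MTX library 1, 2, 4 or 5, and 60, 51 and 72 without MTX+nitrate library 1, 2 or 3. It was 42, 66, 79 and 76 without control library 1, 3, 4 or 5, and 69 after the length and GC correction.

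A score over 180 MTX-responsive genes, 92 higher and 88 lower in both MTX groups pooled than in control, did not show a difference between the treated groups. It was -0.643 ± 0.264 in control, 1.2 ± 0.345 in MTX and 1.19 ± 0.216 in MTX+nitrate (difference -0.012, two-sided exact permutation p = 0.944). Choosing genes on both treated groups favours those the groups share, and genes that nitrate returned to control tend to be left out. In simulated data with the effect halved alike in every changed gene, the score found the difference in 10 of 10 runs. Those runs held no genes returned to control, so they do not address this choice. The score therefore leaves open whether nitrate returned other genes. Genes called in both comparisons with control numbered 45 higher in both, 30 lower in both and 1 opposite. Independent lists would give 4.14 and 2.26. With the shared controls, simulations that left out both effects gave 0, and split controls, with both effects kept but smaller control groups, gave 3.1 and 0.3. The excess over these values is not a measure of a shared effect. The covariance of these fold changes was 0.0957, against 0.0406 in simulations and 0.0539 with split controls, and their correlation across genes 0.511 against 0.498.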

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

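The tests of clock time were chosen after their results were seen. Within each group, libraries that stood apart were looked for by Dixon's criterion in log2 CPM. Among 459 groups of 5 values, 26 held such a library, where 23 are expected by chance.

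Genes with 1 low library were Ctgf in control 3 (1.99 CPM, others 4.06 to 5.29), Leng8 in control 2 (38.2, others 53.4 to 56.1) and Xbp1 in control 2 (221, others 298 to 333). In MTX these were Lgr5 in library 1 (2.28, others 3.81 to 4.45), Dhcr7 in library 5 (135, others 185 to 205) and mt-Atp6 in library 4 (134, others 286 to 365). In MTX+nitrate they were C1qtnf1 in library 5 (9.86, others 13.9 to 14.8), Cyp3a11 in library 5 (1940, others 3170 to 3600), Sp5 in library 5 (0.225, others 1.36 to 2.09) and Mmp9 in library 5 (0, others 0.245 to 0.424). Cyp2c50 in MTX+nitrate 1 was at 352 CPM (others 439 to 467), Per1 in MTX+nitrate 1 at 13.9 (others 28.5 to 33.9) and Per3 in MTX+nitrate 2 at 1.38 (others 3.29 to 3.97).

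Genes with 1 high library were Cp in control 5 (1930 CPM, others 1620 to 1690), Fasn in control 2 (1420, others 364 to 496), Glrx in control 1 (58, others 44.9 to 46.9) and Per3 in control 1 (38.9, others 5.56 to 9.4). In MTX they were Apobec1 in library 1 (68.4, others 25.1 to 33.4), Dbp in library 3 (5.06, others 0.246 to 0.484) and Sp5 in library 4 (1.66, others 0.527 to 0.725). In MTX+nitrate they were Ccl2 in library 1 (1.1, others 0.225 to 0.275), Cyp2c29 in library 4 (3390, others 2120 to 2280), Dnajb1 in library 4 (47.4, others 19.8 to 23.8) and Plekhg1 in library 3 (9.52, others 6.15 to 6.91). The 10 most abundant genes held 17% of counts in control 1 (others 19 to 19.7%), and haemoglobins 0.00888% in MTX 1 (others 0.00319 to 0.0042%).

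Most called clock genes were lower in both treated groups than in control. A score over 10 clock genes, whether called or not, the mean log2 CPM of those known to fall over the light phase minus that of those known to rise, was -0.966 ± 1.334 in control, 1.685 ± 1.144 in MTX (exact p = 0.0159) and 1.863 ± 0.174 in MTX+nitrate (exact p = 0.00794). Control library 1 scored -3.142 and the other controls between -1.17 and 0.376, so its collection at another clock time could explain the pattern. Without it, the 5 genes called lower in MTX+nitrate than in control kept a median share of 0.81 of their log2 change. This argues against it as the whole cause in that comparison. There, Tef, Nr1d1 and Per3 lost their calls without it (adjusted p = 0.103, 0.0696 and 0.0967), while Dbp and Nr1d2 kept them (0.0207 and 0.0336). The share was not computed for MTX against control, where Dbp, Nr1d2 and Tef lost their calls without control library 1. Collection of the groups at different clock times and an effect of MTX on the clock cannot be told apart, since no collection time is given.

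The numbers of called genes were beyond chance, and the numbers of called lists were not. In each comparison 1 of 100 splits of the 10 libraries, the real one, called as many genes. The real counts were 521, 613 and 342 for MTX against control, MTX+nitrate against MTX and MTX+nitrate against control, and the highest other counts were 137, 145 and 2. For lists, 10, 13 and 30 of 100 splits called as many as the real 14, 15 and 10, the real one included, and the highest other counts were 15, 17 and 16.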

How the results depend on the processing

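The length and GC correction and the exact permutation of list means were chosen after the data were seen. The causes of the differences below were not tested, except that stricter thresholds call fewer genes by construction. Genes called for MTX against control numbered 521. They numbered 1141 by DESeq2, 43 at an adjusted p under 0.01, 133 at a log2 fold change of at least 1, and 86 to 995 when 1 library was left out. For MTX+nitrate against MTX the 613 genes became 1167 by DESeq2, 384 without an expression filter, 294 after the length and GC correction, 248 in a fit over 2 groups, 30 at an adjusted p under 0.01, 99 at a log2 fold change of at least 1, and 166 to 600 without 1 library. For MTX+nitrate against control the 342 genes became 752, 220 after the length and GC correction, 46 and 114 at the stricter thresholds, and 99 to 312 without 1 library. The genes past both thresholds in opposite directions, 141, became 86 without an expression filter, 69 after the length and GC correction, 4 and 30 at the stricter thresholds, 2.55 with the MTX libraries split, and 17 to 227 without 1 library.

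Gene lists called numbered 14, 15 and 10. By camera with an estimated correlation, and by exact permutation of list means, 0 passed in each comparison (lowest exact adjusted p = 0.0714, 0.0714 and 0.0952). The smallest possible exact p is 0.0079, and over 36 lists a single list at it cannot pass after adjustment. The exact test therefore does not show that the lists were unchanged. At an unadjusted exact p under 0.05 there were 11, 10 and 5, and fry called 2, 10 and 1. Without 1 library the numbers were 7 to 16, 12 to 17 and 4 to 11, and after the length and GC correction the last was 6. The share of MTX-changed genes that moved back stayed between 82.6 and 100%, and the signature score between -0.167 and 0.086 over these settings.

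The replicate numbers did not pair the libraries. Same-number libraries had correlations of their deviations from -0.194 to 0.0636, with 0 of 15 above 0.1. A fit with the replicate number as a block called 142, 129 and 155 genes and 20 in opposite directions, and did not call 23, 33 and 13 of the named genes called without it. For library measures, exact permutation with the block exchanges libraries only within a replicate number. That leaves too few assignments for any exact p under 0.05, so no measure could pass (lowest adjusted p = 0.25). This test therefore cannot show whether the groups differed in these measures. The block ended the Kupffer cell list call in both comparisons with MTX (adjusted p = 0.0625 and 0.0552).

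No named gene or list called in either of the settings compared changed direction. Where neither setting called it, direction turned in 106 of 1941 comparisons of a list with its reported result, over 31 of 108 list results, and in 27 of 3599 for named genes. Of those for lists, 78 came from leaving out 1 library, 8 from the length and GC correction, 8 from the exact permutation and 3 from fry (nitric oxide handling for MTX against control, purine and pyrimidine synthesis for MTX+nitrate against MTX and Wnt components for MTX+nitrate against control). The score, which was not called, turned in 6 of 16. Of the 54, 61 and 34 calls of named genes for MTX against control, MTX+nitrate against MTX and MTX+nitrate against control, 8, 23 and 9 were lost after the length and GC correction, 11, 14 and 3 in a fit over 2 groups, 14, 7 and 2 with limma-voom, 6, 8 and 0 without an expression filter, and 4, 0 and 1 with median-of-ratios size factors. DESeq2 ended none of these calls and called 11, 5 and 6 further named genes. Counting depth limits the genes under about 2 CPM most. Among the named genes that lie there in at least 1 group are Rspo1, S100a8, Mmp9, Chil3 and F13a1. Dbp, Ccl2, Itgax, Il1b, Il1rn, Top2a and Sp5 do so as well.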

Other observations

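The tests on Neat1 and Malat1, on glucocorticoid-responsive genes, on clock time, on the calls kept after the length and GC correction, and that correction itself, were chosen after their results were seen. Neat1, a nuclear non-coding RNA, was at 195 ± 31.4 CPM in control, 100.5 ± 27.6 in MTX (adjusted p = 0.0325) and 269 ± 94.4 in MTX+nitrate (adjusted p against MTX = 0.0073). With the nuclear RNA Malat1, it held 0.0486 ± 0.0049% of counts in control, 0.0275 ± 0.0044% in MTX (exact p = 0.00794) and 0.0537 ± 0.018% in MTX+nitrate (exact p against MTX = 0.0159, adjusted p = 0.0239 for both over 9 tests).

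For genes changed by MTX that went the other way with nitrate, all assignments of the 10 treated libraries to MTX and MTX+nitrate were compared. Only 1 assignment, the real one, gave a covariance of mean log2 CPM differences as negative (share 0.00397). The margin was narrow (-0.0885 against -0.0879). This argues against chance values of the shared MTX libraries where the treated groups are otherwise alike. However, a difference between the treated groups in any direction also tends to make this covariance more negative. The test therefore cannot show that genes moved back towards control. Transcript length bias could also produce opposite changes. Across genes, fold change correlated with transcript length at -0.266 for MTX against control and at 0.265 for MTX+nitrate against MTX. With GC content these values were 0.161 and 0.153, so a GC trend by itself pointed the same way in both comparisons. Of the 141 genes called in opposite directions, 49 stayed so after the length and GC trends were removed. This argues against length bias as the whole cause for those. Their median change went from 0.839 to 0.713 with MTX and from 0.759 to 0.616 with nitrate, and that of the 92 others from 0.488 to 0.416 (a ratio of 0.851) and from 0.47 to 0.364, with median ratios per gene of 0.96 and 0.978 for the 49 and of 0.85 and 0.789 for the 92. The 92 started from smaller changes against a median SE of 0.106, and for them bias and an effect of nitrate cannot be told apart.

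Of 20 fasting genes, 5 were called higher in MTX+nitrate than in MTX (8 higher and 2 lower when adjusted over the list alone), and the list was not called with an estimated correlation (adjusted p = 0.256). All 5 stayed called after the length and GC correction, which argues against transcript length or GC bias of the libraries as the whole cause. Collection at another clock time may also raise Per1, and the clock score, which did not differ detectably between the treated groups (exact p = 0.825), leaves this open without collection times. A candidate explanation is higher glucocorticoid signalling, to which Tsc22d3 and Per1 of the 5 respond, and also Tat, which is not among the 5. The mean log2 CPM of 12 more glucocorticoid-responsive genes was higher by 0.372 in MTX+nitrate than in MTX (6.01 ± 0.243 against 5.64 ± 0.284, exact p = 0.0635). Of the 12, Lpin1 is itself in the fasting list, and Mt1, Mt2, Dusp1 and Sds are in other lists. However, 5 of the 12 were lower, none passed the test, and Ddit4 (1.29) and Errfi1 (0.89) had the highest log2 changes. The mean was also already higher in MTX than in control (by 0.463, unadjusted exact p = 0.0238). The hypothesis of higher glucocorticoid signalling is therefore neither excluded nor shown.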
